A study of Arabidopsis thaliana with 6 samples.

How the data were processed

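Whole seedlings of Arabidopsis thaliana, wild-type Columbia and the nf-ycQ T-DNA mutant in the same background, were grown for 2 days under red light of 20 µmol per m2 per s on medium with 0.3% sucrose and 0.8% agar. Total RNA was the source of 3 sequenced libraries per genotype. The labels give replicate numbers and do not say whether replicates were separate cultures, so p-values measure the spread between these samples, which may be technical. Samples were grouped by title.

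The authors deposited 1 table per library with RPKM values (reads per kilobase of gene model, scaled to library size) for 33602 genes. The unit was read from the values, since the file headers name only the gene and the library, and whether reads or fragments were counted is not given in the sources used here. Alignment used TopHat2 2.0.9 and Bowtie2 2.0.6 on the TAIR10 build, per the submitters' processing notes. The read counter, the annotation release and the strand setting are not given in the sources used here. Overlapping and antisense genes, and families with near-identical copies (the LHCB1, RBCS, SESA and SAUR19 to SAUR24 genes), can therefore share, swap or lose reads.

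The depth behind the values was read from their steps. Within a library, the RPKM values of a gene are whole multiples of the worth of 1 read, which depends on gene length and on the library total. For each library the total was taken that made the most genes of known exon length (RefSeq annotation of TAIR10.1) a whole number of reads. With these totals, 100.0% of the 24572 genes above 0 came out as whole reads within a tolerance of 0.02 reads, 3063 with the annotated length and 21509 with another length, taken as the shortest plausible one that gave whole reads. That length was free to vary, so the share of whole values is weak evidence. The summed reads came to between 99.95% and 100.01% of the totals. This sum is not an independent check, because a first rule, the length nearest to the annotated one, gave sums above the totals and was replaced for that reason. The recovered reads of single genes therefore rest on this rule, while the main test uses the RPKM values. On simulated data of 4000 genes with known counts, all 6 totals and all counts of 99.1% of genes above 0 were recovered. The totals were 14462520, 11289104 and 12905110 reads for wild-type replicates 1 to 3, and 14235027, 12538754 and 13326170 for nf-ycQ replicates 1 to 3. One read in a gene of 1 kb is worth 0.0691 to 0.0886 RPKM. The reads carry no molecular identifiers, so precision from counts covers counting error only. No replicate pair was closer than counting noise allows, with a mean chi-square per gene of 3.08 to 12.4.

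The 18937 genes with at least 1 RPKM in at least 3 libraries were tested on log2(RPKM + 1) with limma 3.58.1 in R 4.3.3 (a mean-variance trend, robust empirical Bayes, 2-sided, genotype as the sole term). P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Fold changes are nf-ycQ over wild type on the log2(RPKM + 1) scale, which understates changes of low genes. Levels are given as mean ± SD over 3 libraries. Simulated data with the spread of these libraries, 18937 genes and 200 changed genes were tested first. Of the genes changed by 0.5, 1 and 2 on the log2 scale, 42.6%, 83.3% and 98.5% were recovered, all in the right direction, with 9 unchanged genes called. Genes were drawn independently there, and far fewer were changed than the 6188 called in the data. These shares therefore do not carry over to the main test.

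Before the data were examined, 20 gene lists with 309 members were fixed by symbol and locus, including markers of other organs and stages (photosynthesis for shoot, root hair for root, seed storage for residual embryo, clock for harvest time, cell cycle for dividing cells). A member was kept where its symbol matched that locus in the RefSeq TAIR10.1 gene table, which dropped 4. Of the 33602 locus names, 32835 were found in that table. It was used for names, gene neighbours and lengths, and no coordinates are given, since the deposited tables hold none and name no annotation. All lists except the NF-YC family were tested against the other genes with camera at a preset inter-gene correlation of 0.01 and adjusted over the 19 lists. Camera with an estimated correlation and fry were the alternatives. The genes named in the text were chosen by a rule fixed at the same time. It takes every NF-YC gene, then the 10 largest rises and 10 largest falls among nuclear genes past the threshold with at least 5 RPKM on average and non-overlapping genotypes, then up to 4 members of each list with the smallest p-value.

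Alternatives were quantile, median-of-ratios and upper-quartile scaling, no filter on low values, a minimum of 5 RPKM in 3 libraries, a pseudocount of 0.1, the replicate number as a block, removal of organelle genes, removal of each library in turn, removal of the 50 genes with most reads, and limma's voom on the recovered reads. Count models planned for deposited counts were not used, because the tables hold normalized values. Python 3.11.15 was used for reading the tables and for figures.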

Results

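Steady-state transcript levels were measured by RNA sequencing in whole seedlings after 2 days of red light, in 3 wild-type and 3 nf-ycQ libraries. NF-YC proteins are histone-fold subunits of the trimeric NF-Y transcription factor, and nf-ycQ carries T-DNA insertions in several of their genes. Library totals inferred from the steps of the RPKM values were 11289104 to 14462520 reads, and 22524 to 22757 genes lay above 0. Genotype was the main axis of variation. The first principal component took 73.2% of the variance and separated the genotypes. Pearson correlations of log2(RPKM + 1) were 0.985 to 0.993 within a genotype and 0.955 to 0.962 between genotypes.

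The mutated genes were examined first, as a check of the labels. The labels do not list them. Published work on this quadruple mutant names NF-YC1, NF-YC3, NF-YC4 and NF-YC9, and these transcripts showed the 4 smallest p-values of the family. NF-YC3 (AT1G54830) fell from 19.9 ± 0.613 RPKM in wild type to 0.468 ± 0.236 RPKM in nf-ycQ, which is 276 to 351 reads per wild-type library against 3 to 11 reads per mutant library. NF-YC9 (AT1G08970) fell from 28.2 ± 1.75 to 4.42 ± 0.344 RPKM, NF-YC1 (AT3G48590) from 24.9 ± 1.54 to 7.69 ± 0.844 RPKM, and NF-YC4 (AT5G63470) from 41.3 ± 3.45 to 15.7 ± 0.550 RPKM. Their adjusted p-values ranged from 3.95e-07 to 5.73e-06. NF-YC2 (AT1G56170), which is not among the published insertions, also fell, from 5.53 ± 0.773 to 2.06 ± 0.685 RPKM (adjusted p = 0.0011). The remaining tested members did not pass the threshold. NF-YC10 stood at 15.9 and 18 RPKM in wild type and mutant (adjusted p = 0.073), NF-YC11 at 21.6 and 21.6 RPKM (adjusted p = 0.97), NF-YC12 at 4.85 and 3.49 RPKM (adjusted p = 0.067) and NF-YC13 at 6.62 and 7.62 RPKM (adjusted p = 0.29). Thus 5 of 9 tested members fell and none rose. Adjusted over the list alone, 6 fell and 1 rose. NF-YC12 passed under quantile, median-of-ratios and upper-quartile scaling (adjusted p = 0.049, 0.042 and 0.048) and without nf-ycQ replicate 3 (adjusted p = 0.021), among other alternatives. NF-YC5, NF-YC6 and NF-YC7 were listed at 0 in all libraries, and NF-YC8 at 0.0867 and 0.227 RPKM lay below the filter. Gene-level RPKM cannot separate full-length from truncated transcripts of an insertion allele, and gene models on the other strand overlap NF-YC2, NF-YC3, NF-YC4 and NF-YC11 (strand not given), so their values are uncertain to that extent. The same holds for the later-named RAB18, CT-BMY, AT2G14247, NF-YB2, LHCB4.2, PORB, CPD, DET2, SOB7, GASA6, XTH15, OLEO2, EXPA7, EXPA18, KNOLLE, TT4, FLC, HSP17.4, HDA2, CDKB2;1, CO, HSP101, LHCB6 and BHLH038, and for MIR156f, CHLD and FER4 with a model on their own strand.

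**Figure D1:**
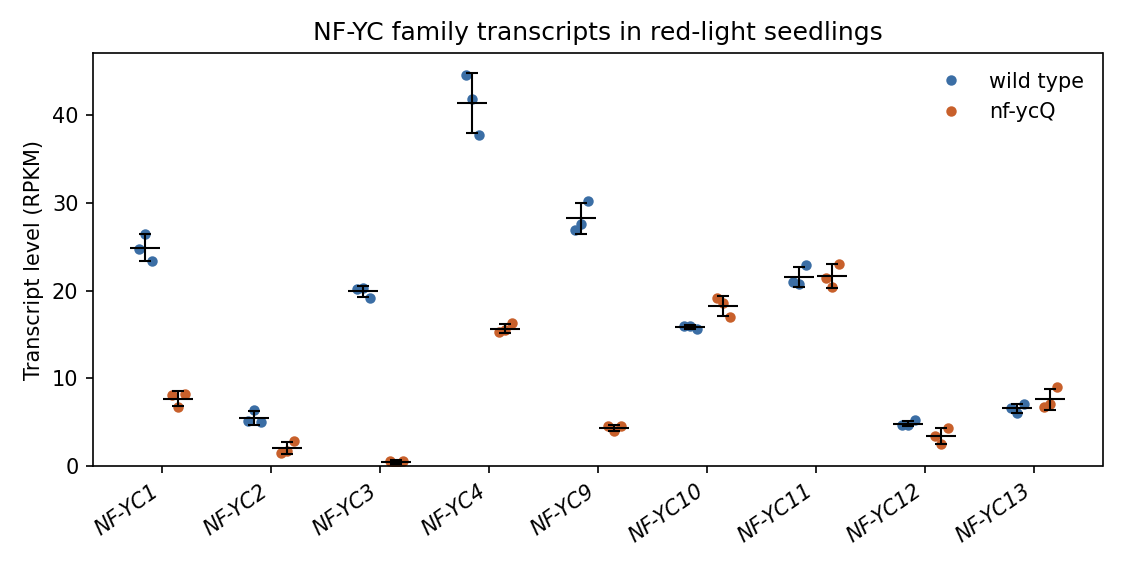
Transcript levels (RPKM, linear axis from 0) of the 9 tested NF-YC genes. Points are single libraries of wild type (blue) and nf-ycQ (orange), and black bars give the mean ± SD of 3 libraries; NF-YC1, NF-YC2, NF-YC3, NF-YC4 and NF-YC9 lie lower in every nf-ycQ library.

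Across all tested genes, 3743 were higher and 2445 lower in nf-ycQ at an adjusted p under 0.05, which is 32.7% of 18937 genes, and 375 and 488 of these changed by at least 1 on the log2 scale. The largest rise was in PORA (AT5G54190), a light-repressed protochlorophyllide oxidoreductase, from 5.48 ± 1.15 to 217 ± 9.89 RPKM (log2 fold change 5.09 ± 0.11 SE, adjusted p = 6.15e-08). NF-YB8 (AT2G37060), a partner subunit of NF-YC, rose from 8.43 ± 0.470 to 111 ± 1.60 RPKM (3.57 ± 0.06 SE, adjusted p = 1.75e-08). The oil-body protein gene OLEO3 (AT5G51210) rose from 2.18 ± 0.212 to 31.0 ± 4.1 RPKM, the dehydrin gene RAB18 (AT5G66400) from 6.17 ± 1.96 to 50.3 ± 6.08 RPKM, and M17 (AT2G41260), annotated as a late embryogenesis abundant protein, from 7.10 ± 2.57 to 48.1 ± 7.90 RPKM. The other rises of this rank were in the microRNA gene MIR156f (AT5G26147), which overlaps another model on the same strand, PELPK1 (AT5G09530), the glycine-rich protein gene AT4G33610, AT4G36850 and AT3G43850, with log2 fold changes of 2.53 to 2.77. The largest falls were in the defensin-like gene AT1G13609, from 120 ± 58.3 to 2.31 ± 0.630 RPKM, and in BHLH100 (AT2G41240), an iron-responsive transcription factor gene, from 22.4 ± 14.5 to 0.260 ± 0.188 RPKM; both varied widely among wild-type libraries. CT-BMY (AT4G17090), a chloroplast beta-amylase gene, fell from 29.4 ± 1.45 to 1.14 ± 0.443 RPKM, NDA1 (AT1G07180), an alternative NAD(P)H dehydrogenase gene, from 15.3 ± 0.718 to 0.448 ± 0.0960 RPKM, and the thionin gene THI2.2 (AT5G36910) from 21.6 ± 1.85 to 1.14 ± 0.117 RPKM. NF-YC3, CGLD27 (AT5G67370), AT3G55240, AT2G32550 and AT2G14247 completed the 10 largest falls, at log2 fold changes of -3.37 to -3.84. Of these, CGLD27, AT3G55240 and AT2G14247 also varied widely among wild-type libraries, at 66.7 ± 22.4, 19.4 ± 6.80 and 76.0 ± 32.8 RPKM. BHLH100 lost its call with voom on recovered reads (adjusted p = 0.17). The split between higher and lower genes depended on scaling: 60.5% of called genes were higher as deposited, 49.8% after quantile normalization, 48.1% after upper-quartile and 44.9% after median-of-ratios scaling, and 50.1% (2818 higher and 2804 lower) without the 50 genes with most reads. Without wild-type replicate 2 the totals were 2462 higher and 1627 lower, and without nf-ycQ replicate 2 they were 2182 and 1826.

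**Figure D2:**
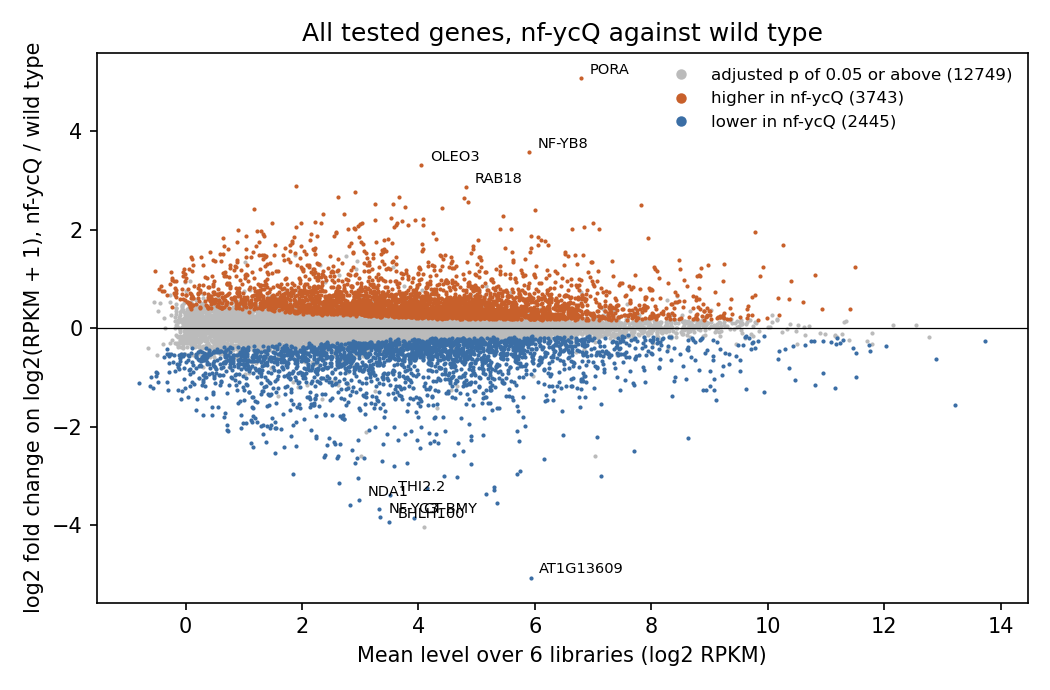
Fold change of nf-ycQ over wild type on log2(RPKM + 1) (vertical axis) against the mean level over 6 libraries in log2 RPKM (horizontal axis) for 18937 genes. Orange points are the 3743 genes higher and blue points the 2445 genes lower in nf-ycQ, grey points did not pass the threshold, and PORA lies highest at 5.09.

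Genes of the NF-Y partners were compared next, because NF-YC acts with NF-YA and NF-YB. Of 14 tested, 6 rose, 2 fell and 6 did not pass the threshold, with the same counts adjusted over the list alone. None fell without wild-type replicate 2 or 3 or nf-ycQ replicate 2, and 1 fell without wild-type replicate 1 or nf-ycQ replicate 1 or 3. Without wild-type replicate 3 or nf-ycQ replicate 1 or 3 only 13 were tested. NF-YB10 (AT3G53340) rose from 14.1 ± 1.70 to 47.0 ± 3.75 RPKM, NF-YB3 (AT4G14540) from 68.2 ± 2.36 to 97.0 ± 9.66 RPKM, and NF-YB2 (AT5G47640) from 40.9 ± 3.12 to 52.9 ± 1.06 RPKM. The list as a whole did not pass camera (adjusted p = 0.064, and adjusted p = 0.39 with an estimated correlation), and over the other camera alternatives its adjusted p ranged from 0.0041 to 0.11. It passed under all 3 rescalings, with a minimum of 5 RPKM, without wild-type replicate 2 (adjusted p = 0.036) and without nf-ycQ replicate 2 (adjusted p = 0.046). Histone deacetylase genes included 4 that rose, 1 that fell and 7 that did not pass among 12 tested, the same counts as adjusted over the list alone. The rises numbered 2 without wild-type replicate 1 or 2 or nf-ycQ replicate 1, and 1 without nf-ycQ replicate 2 or 3. None fell without wild-type replicate 2 or nf-ycQ replicate 1. Without any 1 nf-ycQ library 11 were tested, because HDA18 lay under 1 RPKM in wild type and dropped out. HDA18 (AT5G61070) moved from 0.270 ± 0.124 to 1.19 ± 0.0883 RPKM (adjusted p = 0.0030) and HDT3 (AT5G03740) from 38.5 ± 1.37 to 46.2 ± 1.91 RPKM (adjusted p = 0.013). HDA14 (AT4G33470) fell from 32.4 ± 1.55 to 27.0 ± 1.07 RPKM. HDA2 (AT5G26040) rose from 4.15 ± 0.467 to 5.69 ± 0.603 RPKM. HDT3 lost its call after median-of-ratios and upper-quartile scaling (adjusted p = 0.058 and 0.051) and without wild-type or nf-ycQ replicate 2 (adjusted p = 0.067 and 0.066), HDA14 without wild-type replicate 2 or nf-ycQ replicate 1 (adjusted p = 0.065 and 0.057), and HDA2 under 8 alternatives (adjusted p = 0.060 to 0.10), which include the 3 rescalings and the removal of replicate 1 or 3 of either genotype. The list did not stand apart (camera adjusted p = 0.41, and adjusted p = 0.65 with an estimated correlation).

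Photosynthesis genes, markers of green shoot tissue, were mostly lower in nf-ycQ, by modest amounts: 16 of 28 fell, 1 rose and 11 did not pass, with a median log2 fold change of -0.27. Adjusted over the list alone, 17 fell and 1 rose. RBCS1A (AT1G67090), a Rubisco small subunit gene, fell from 14155 ± 292 to 4811 ± 397 RPKM and from 1.45% to 0.492% of all reads. RBCS1B (AT5G38430) fell from 2469 ± 185 to 1112 ± 112 RPKM, and the chlorophyll-binding antenna genes LHCB4.1 (AT5G01530) and LHCB4.2 (AT3G08940) from 3183 ± 158 to 1365 ± 66.3 RPKM and from 1921 ± 196 to 925 ± 94.5 RPKM. LHCB2.2, the 1 member that rose and named after its value was seen, stood at 1701 and 2215 RPKM. The list passed camera (adjusted p = 1.13e-06; adjusted p = 0.45 with an estimated correlation). After quantile normalization 8 fell and 4 rose, with a median of -0.07, and without wild-type or nf-ycQ replicate 2 the falls numbered 10 and 9. Chlorophyll synthesis genes moved in both directions. PORA and PORB (AT4G27440), which encode protochlorophyllide oxidoreductases, rose, PORB from 580 ± 17.0 to 1865 ± 22.1 RPKM. CHLD (AT1G08520), a magnesium chelatase subunit gene, rose from 146 ± 9.14 to 229 ± 8.87 RPKM, and CHLG (AT3G51820), the chlorophyll synthase gene, fell from 123 ± 7.39 to 69.9 ± 2.40 RPKM. In all, 4 of 14 rose, 6 fell and 4 did not pass, against 6 and 7 adjusted over the list alone. The list's median was -0.16 and its mean 0.35, and camera did not call it (lower, adjusted p = 0.41; adjusted p = 0.56 with an estimated correlation).

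Light signalling genes included 6 that rose, 2 that fell and 5 that did not pass among 13 tested, the same counts as over the list alone. PHYA (AT1G09570), the light-labile phytochrome, rose from 80.8 ± 1.02 to 166 ± 1.69 RPKM (adjusted p = 2.14e-06). The light-promoting regulators BBX21 (AT1G75540) and HY5 (AT5G11260) rose from 47.9 ± 3.86 to 79.1 ± 3.27 RPKM and from 19.8 ± 2.78 to 38.2 ± 3.1 RPKM, and the early light-induced gene ELIP2 (AT4G14690) fell from 46.5 ± 11.2 to 14.7 ± 1.57 RPKM. The list was not called by camera (adjusted p = 0.49, and adjusted p = 0.56 with an estimated correlation). Among PIF factors and their shade or growth targets, 6 of 14 rose, none fell and 8 did not pass, and over the list alone the counts were unchanged. PIF4 (AT2G43010), a growth-promoting bHLH factor, rose from 21.2 ± 0.619 to 38.6 ± 5.72 RPKM. PRE5 (AT3G28857) rose from 0.633 ± 0.0993 to 2.19 ± 0.329 RPKM, PRE1 (AT5G39860) from 9.19 ± 1.13 to 14.7 ± 0.643 RPKM, and BBX28 (AT4G27310) from 26.3 ± 4.37 to 39.3 ± 2.93 RPKM. Camera gave adjusted p = 0.069 for this list, and adjusted p = 0.39 with an estimated correlation. It passed after quantile normalization (adjusted p = 0.0496), without a filter (adjusted p = 0.033) and without wild-type replicate 1 (adjusted p = 0.038), in a range of 0.033 to 0.18 over the other camera alternatives.

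Of 29 auxin genes, 14 rose, 1 fell and 14 did not pass, with a median log2 fold change of 0.38, and 16 rose and 1 fell when adjusted over the list alone. Without nf-ycQ replicate 2 the rises numbered 9. IAA6 (AT1G52830), an auxin-induced repressor gene, rose from 1.04 ± 0.106 to 9.21 ± 0.451 RPKM, GH3.5 (AT4G27260), an auxin-conjugating enzyme gene, from 21.0 ± 1.39 to 38.6 ± 0.458 RPKM, and IAA19 (AT3G15540) from 24.4 ± 5.0 to 46.6 ± 4.0 RPKM. SAUR16 (AT4G38860) fell from 29.2 ± 6.79 to 8.99 ± 0.625 RPKM. The list passed camera (adjusted p = 0.0073; adjusted p = 0.45 with an estimated correlation). Cell-wall loosening genes were divided, with 8 of 22 higher, 7 lower and 7 not past the threshold; 10 rose and 7 fell over the list alone. XTH15 (AT4G14130) rose from 32.3 ± 6.39 to 112 ± 18 RPKM, whereas EXPA1 (AT1G69530) fell from 134 ± 3.04 to 66.5 ± 4.32 RPKM, XTH31 (AT3G44990) from 116 ± 8.97 to 50.4 ± 4.55 RPKM and EXPA5 (AT3G29030) from 47.3 ± 1.02 to 28.1 ± 1.99 RPKM. The median of this list was 0.10 and its mean 0.08, while camera placed it lower without a call (adjusted p = 0.73, and adjusted p = 0.73 with an estimated correlation).

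Of 19 gibberellin genes, 8 rose, 3 fell and 8 did not pass, with 9 and 3 over the list alone. The rises numbered 4 without wild-type replicate 2 and 5 without nf-ycQ replicate 2, and 1 gene fell without nf-ycQ replicate 3. The gibberellin-regulated genes GASA4 (AT5G15230) and GASA1 (AT1G75750) rose from 918 ± 11.4 to 1404 ± 60.4 RPKM and from 281 ± 40.4 to 507 ± 63.2 RPKM, and GASA6 (AT1G74670) fell from 355 ± 44.5 to 206 ± 24.1 RPKM. Of 12 brassinosteroid genes, 4 rose, none fell and 8 did not pass, the same counts as over the list alone, and 1 fell without wild-type replicate 3. The synthesis genes DET2 (AT2G38050) and CPD (AT5G05690) rose from 13.8 ± 0.200 to 19.7 ± 0.283 RPKM and from 49.1 ± 5.12 to 74.0 ± 5.60 RPKM, the catabolic gene SOB7 (AT1G17060) from 9.71 ± 1.29 to 15.0 ± 0.943 RPKM and the receptor gene BRI1 (AT4G39400) from 32.6 ± 1.48 to 39.7 ± 1.67 RPKM. Neither hormone list was called by camera (adjusted p = 0.31 and 0.16; adjusted p = 0.45 and 0.49 with an estimated correlation).

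Seed storage, oil-body and late embryogenesis genes, markers of residual embryo programme, were higher in nf-ycQ: 12 of 14 rose, 1 fell and 1 did not pass, both over all genes and over the list alone, with a median log2 fold change of 1.68. Without nf-ycQ replicate 1, 2 or 3, where 13 were tested, the rises numbered 11, 9 and 9. None fell without wild-type replicate 2 or 3, or without nf-ycQ replicate 1 or 2. PER1 (AT1G48130), a seed peroxiredoxin gene, rose from 2.37 ± 0.303 to 12.7 ± 1.2 RPKM, OLEO2 (AT5G40420) from 2.80 ± 0.753 to 16.2 ± 2.04 RPKM, the 2S albumin gene SESA3 (AT4G27160) from 3.48 ± 0.931 to 23.7 ± 4.79 RPKM, and EM6 (AT2G40170) from 4.04 ± 1.2 to 20.9 ± 2.98 RPKM. The list passed camera (adjusted p = 6.22e-06; adjusted p = 0.39 with an estimated correlation). Of 11 abscisic acid genes, 7 rose, 2 fell and 2 did not pass, also over the list alone. The rises numbered 4 without nf-ycQ replicate 1 or 2, where 10 were tested, and none fell without wild-type replicate 1, 2 or 3, where 9 were tested. Besides RAB18, RD29B (AT5G52300) rose from 1.79 ± 0.0526 to 7.41 ± 0.951 RPKM, RD29A (AT5G52310) from 12.9 ± 0.951 to 34.9 ± 5.0 RPKM and ABI5 (AT2G36270), a transcription factor of the abscisic acid response, from 2.37 ± 0.392 to 6.78 ± 0.549 RPKM. This list missed the camera threshold (adjusted p = 0.064; adjusted p = 0.39 with an estimated correlation) and over the other camera alternatives ranged from adjusted p = 5.19e-04 to 0.10. It passed under each rescaling and, with 9 tested, without wild-type replicate 1, 2 or 3 (adjusted p = 5.19e-04, 5.53e-04 and 0.0014). None of these 9 fell, against 2 of 11 over all libraries, so the passes without a wild-type library may follow from the filter.

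Root hair genes, markers of root epidermis, were lower in nf-ycQ: 9 of 10 fell and none rose, both over all genes and over the list alone, with a median log2 fold change of -1.08. The cell-wall protein genes PRP3 (AT3G62680) and PRP1 (AT1G54970) fell from 168 ± 1.82 to 63.2 ± 7.14 RPKM and from 72.7 ± 1.41 to 25.9 ± 3.55 RPKM, and the root hair expansin genes EXPA7 (AT1G12560) and EXPA18 (AT1G62980) from 60.3 ± 3.16 to 27.4 ± 1.18 RPKM and from 51.6 ± 3.70 to 23.8 ± 1.24 RPKM. The list passed camera (adjusted p = 1.16e-08; adjusted p = 0.20 with an estimated correlation). Clock genes changed in 13 of 14 cases, 10 higher and 3 lower, likewise over the list alone. GRP7 (AT2G21660), a clock-regulated RNA-binding protein gene, rose from 1148 ± 45.7 to 2435 ± 116 RPKM, PRR7 (AT5G02810) from 12.3 ± 1.38 to 35 ± 2.24 RPKM and the evening gene TOC1 (AT5G61380) from 18.0 ± 1.40 to 36.9 ± 0.191 RPKM, while the morning gene RVE8 (AT3G09600) fell from 32.3 ± 0.897 to 16.1 ± 0.660 RPKM. Camera called the clock list higher (adjusted p = 0.015, and adjusted p = 0.28 with an estimated correlation). The call ended with a minimum of 5 RPKM, where 12 were tested (adjusted p = 0.089, with a range from 0.0038 to this value over the other camera alternatives). Of 7 cell cycle genes, 3 rose, the cytokinesis gene KNOLLE (AT1G08560) from 49.4 ± 3.74 to 66.3 ± 7.13 RPKM and the mitotic genes CDKB2;1 and CYCB1;2, 4 did not pass, and over the list alone 4 rose. Without replicate 2 of either genotype the rises numbered 1. CDKB2;1 lost its call without replicate 2 of either genotype (adjusted p = 0.074 and 0.080), and CYCB1;2 under 8 alternatives (adjusted p = 0.051 to 0.094), among them the 3 rescalings. This list was not called (camera adjusted p = 0.076; adjusted p = 0.48 with an estimated correlation), and passed without a filter (adjusted p = 0.047) and without nf-ycQ replicate 1 (adjusted p = 0.041), in a range up to 0.15.

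Flavonoid genes were lower in nf-ycQ: 6 of 10 tested fell, 4 did not pass and none rose, and 9 fell over the list alone, with a median log2 fold change of -1.24. Without wild-type replicate 1 all 10 fell. TT4 (AT5G13930), the chalcone synthase gene, fell from 251 ± 61.9 to 31.6 ± 12.8 RPKM, FLS1 (AT5G08640), the flavonol synthase gene, from 80.0 ± 14.4 to 24.2 ± 4.88 RPKM, TT5 (AT3G55120), the chalcone isomerase gene, from 36.1 ± 6.15 to 18 ± 0.796 RPKM and the flavonol regulator gene MYB12 (AT2G47460) from 4.62 ± 0.312 to 1.42 ± 0.196 RPKM. The list passed camera (adjusted p = 1.13e-06; adjusted p = 0.39 with an estimated correlation). Defence and jasmonate genes were lower in 4 of 7 cases, with none higher and 3 not past the threshold, also over the list alone. The jasmonate synthesis genes LOX2 (AT3G45140) and AOS (AT5G42650) fell from 42.5 ± 6.58 to 6.27 ± 0.182 RPKM and from 39.6 ± 5.80 to 20.0 ± 0.938 RPKM, and VSP2 (AT5G24770) from 4.56 ± 0.848 to 1.28 ± 0.527 RPKM. OPR3, also of jasmonate synthesis, fell from 23.8 ± 1.6 to 19.1 ± 1.4 RPKM and lost its call without nf-ycQ replicate 1 or 2 (adjusted p = 0.060 and 0.056). Camera called this list (adjusted p = 0.0012; adjusted p = 0.20 with an estimated correlation).

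Of 5 tested flowering genes, 3 fell, none rose and 2 did not pass, and the counts were equal over the list alone. FLC (AT5G10140), a floral repressor gene, fell from 10.8 ± 0.795 to 2.44 ± 1.16 RPKM (adjusted p = 7.77e-04), and SVP (AT2G22540) from 11.2 ± 1.09 to 8.05 ± 0.645 RPKM. CO, a photoperiod gene, fell from 1.86 ± 0.768 to 0.710 ± 0.235 RPKM and lost its call without nf-ycQ replicate 1 or 3 (adjusted p = 0.056 and 0.082). It averaged under 1 RPKM in nf-ycQ and dropped out without wild-type replicate 1, 2 or 3, so its fall rests in part on the filter. In those fits 3, 3 and 4 genes of the list were tested, and 2 fell each time. The list passed camera (adjusted p = 0.013, and adjusted p = 0.39 with an estimated correlation). Without wild-type replicate 1, where 3 were tested, it did not (adjusted p = 0.056, with a range from 0.0090 to this value over the other camera alternatives). Of 5 tested heat shock genes, 3 rose, 1 fell and 1 did not pass, as over the list alone. Without any 1 nf-ycQ library 4 were tested, because HSP17.4 lay under 1 RPKM in wild type and dropped out. Without nf-ycQ replicate 2 the rises numbered 1, and none fell without wild-type replicate 2 or 3 or nf-ycQ replicate 1 or 3. HSP17.4 (AT3G46230) moved from 0.180 ± 0.123 to 2.49 ± 0.804 RPKM and HSP90.1 (AT5G52640) from 8.06 ± 0.241 to 13.5 ± 1.40 RPKM. HSP101 rose and lost its call without replicate 2 of either genotype (adjusted p = 0.061 and 0.067). HSP18.2 fell and lost its call with voom (adjusted p = 0.074) and without wild-type replicate 2 or 3 or nf-ycQ replicate 1 or 3 (adjusted p = 0.074 to 0.084). Camera did not call it (adjusted p = 0.20; adjusted p = 0.50 with an estimated correlation).

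**Figure D3:**
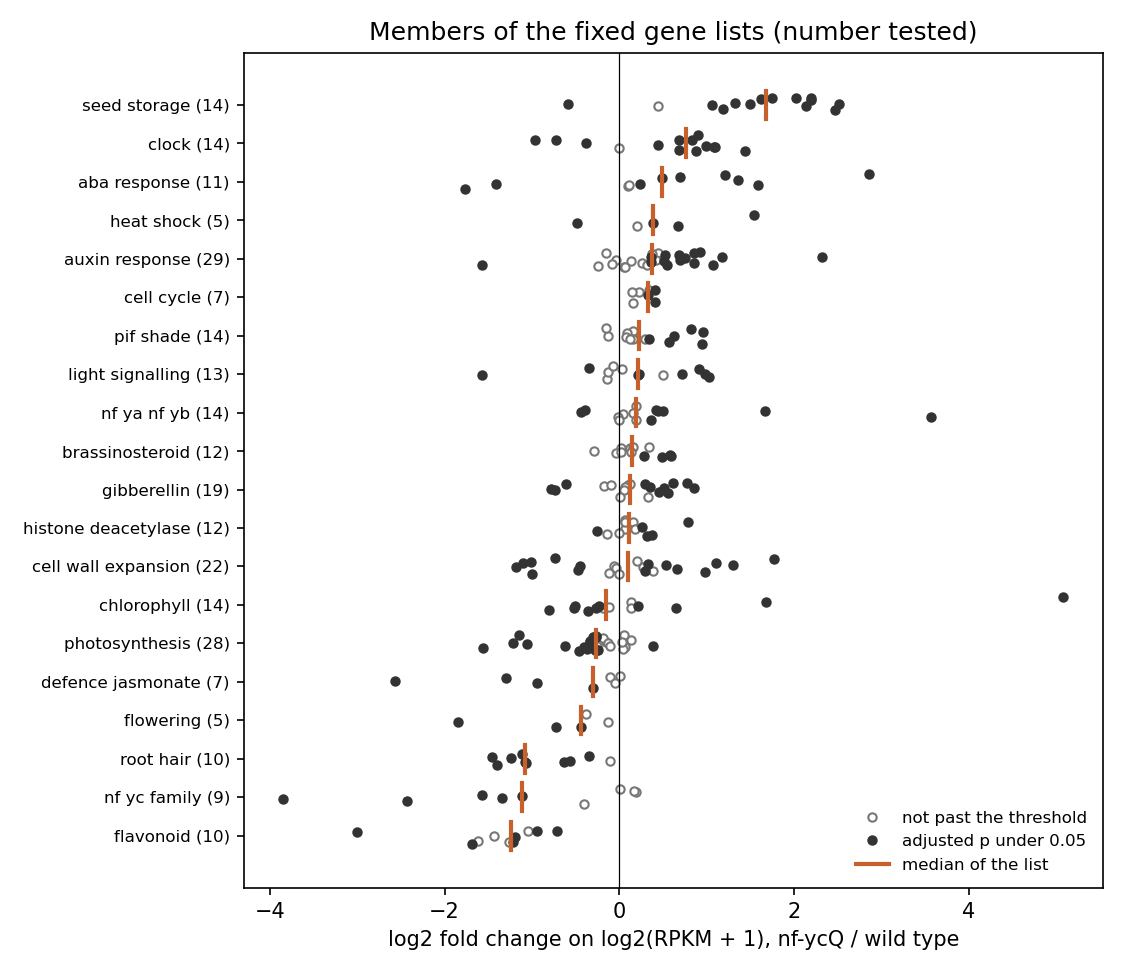
Fold changes of nf-ycQ over wild type on log2(RPKM + 1) (horizontal axis) for the tested members of each fixed gene list (vertical axis, number tested in brackets). Filled points passed an adjusted p under 0.05, open points did not, and orange bars are list medians, from 1.68 for seed storage genes to -1.24 for flavonoid genes.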

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

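The median-of-ratios and upper-quartile scaling of RPKM values, voom on recovered reads and the removal of the 50 genes with most reads were chosen after seeing the data; the other alternatives were chosen before. Of 95 genes named by the fixed rule and past the threshold, 85 kept their call in every one of the 16 alternatives that tested them, and 10 lost it under at least 1. The rule takes the smallest p-values of each list and the largest changes; of all 184 list members and top genes past the threshold, 50 lost their call under at least 1. Some, such as NF-YC3, fell under the filter when a wild-type library was left out. Among all 285 tested list members and top genes, 1 changed sign with a call: LHCB6 stood at 0.17 after quantile normalization (adjusted p = 0.030) and at -0.10 as deposited (adjusted p = 0.43), and the cause was not tested. Leaving out each library in turn gave 4008 to 5881 called genes, 2182 to 3702 higher and 1627 to 2179 lower, and 766 to 818 with at least a 2-fold change; these fits have fewer samples. The count with at least a 2-fold change was 863 and ranged from 646 with the 5 RPKM minimum, which tests fewer genes, to 1236 with voom. Camera called 8 of 19 lists. With an estimated correlation it called 0, and 3 passed an unadjusted p under 0.05. Fry called 18, but asks whether a list's genes move one way and does not compare them with other genes; it placed the chlorophyll list (median -0.16) higher (adjusted p = 0.0017), where camera placed it lower. In the sample relations, the lowest within-genotype correlation exceeded the highest between genotypes by 0.0229, and by 0.0125 without a filter, 0.0328 with the 5 RPKM minimum, 0.0307 with a pseudocount of 0.1 and 0.0285 with voom, and the cause was not tested. With the replicate number as a block, 8530 genes were called, 5418 of them higher, and no list member or top gene lost a call; 10 flavonoid genes fell and 5 cell cycle genes rose, against 6 and 3 without it, 1 brassinosteroid gene fell and 1 NF-YC gene rose, against 0, and 2 photosynthesis genes rose, against 1. Among the groups chosen afterwards, 11 of 12 iron deficiency genes fell with the block, IRT1 and FRO2 (adjusted p = 8.24e-06 and 0.0034) added to the 9, and 1 plastid-encoded gene fell, against 0. Of the late embryogenesis genes by product name 8 fell, against 5, and camera at the preset correlation did not call them (p = 0.055). With the 5 RPKM minimum 5 gibberellin genes rose and 1 fell among 13 tested, against 8 and 3 among 19. No NF-YA or NF-YB, abscisic acid, seed or heat shock gene fell, against 2, 2, 1 and 1. Only 8, 6, 10 and 2 genes of these lists were tested there, so genes can be missing for lack of a test. Of histone deacetylase genes, 4 of 12 rose as deposited and 2 of 10 with that minimum. After quantile normalization or without the 50 genes 2 of 12 rose, and 1 of 12 after the other rescalings. Without a filter no NF-YA, NF-YB or seed gene fell, and with voom 1 NF-YA or NF-YB gene and no seed or heat shock gene fell. Of PIF and target genes 1 fell, against 0, after median-of-ratios or upper-quartile scaling or without the 50 genes. Without the 50 genes, 4 photosynthesis genes of 7 tested fell and none rose, and 2 chlorophyll genes of 12 tested rose. Deviations from the genotype means correlated at 0.38, -0.01 and 0.39 for replicates 1, 2 and 3, and at -0.38 and -0.39 between replicates 1 and 3 across genotypes. The second principal component (13.3% of variance) ran from replicate 1 through 2 to 3 in both genotypes. Along such a shared order replicate 2 lies near the middle, so its low correlation cannot decide whether the numbers pair the samples. The main fit, planned without a block, leaves this spread in its p-values. Count models planned for deposited counts were not run. One read in a 1 kb gene is worth up to 0.0886 RPKM, so levels near the 1 RPKM filter rest on few reads.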

Other observations

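The gene groups of this part were chosen after the results were seen, as were the removal of the 50 genes with most reads and the tests of the choice of scaling, of ungerminated seeds and of harvest time. Iron deficiency genes were lower in nf-ycQ: of 12 tested, 9 fell, none rose and 3 did not pass, with a median log2 fold change of -1.23, and 5 fell with voom on recovered reads. NAS4, a nicotianamine synthase gene, fell from 30.4 ± 5.85 to 6.08 ± 0.0853 RPKM, BTS from 39.5 ± 8.86 to 16.8 ± 0.547 RPKM, and the iron-responsive regulator gene BHLH038 from 15.3 ± 9.04 to 1.33 ± 0.402 RPKM. BHLH038 lost its call with voom (adjusted p = 0.072). The iron uptake genes IRT1 and FRO2 did not pass (adjusted p = 0.21 and 0.19), and FRO2 passed without wild-type replicate 3 (adjusted p = 0.014). Both were lower in nf-ycQ within each replicate number, and both passed with that number as a block (adjusted p = 8.24e-06 and 0.0034). Of 4 ferritin genes, which encode iron storage proteins, 3 rose, FER3 from 72.4 ± 14.9 to 145 ± 13.6 RPKM and FER4 from 47.8 ± 7.42 to 90.7 ± 5.23 RPKM. The same genes also differed among wild-type libraries. From replicate 1 to 3 every iron deficiency gene fell, such as BHLH039 at 42.3, 29.4 and 10.8 RPKM. Every ferritin gene rose over them, such as FER3 at 56.6, 74.4 and 86.2 RPKM. Camera gave p = 1.15e-07 for iron deficiency and p = 0.012 for ferritin genes, and p = 0.16 and 0.26 with an estimated correlation.

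Of 84 tested plastid-encoded genes, 55 rose and none fell, with a median log2 fold change of 0.97 (camera p = 8.71e-15, and p = 0.014 with an estimated correlation). Of 14 mitochondria-encoded genes, 9 rose and none fell, with a median of 0.77 (camera p = 0.0032, and p = 0.035 with an estimated correlation). Without nf-ycQ replicate 1, 2 or 3 only 6 of the latter were tested, 2 rose each time, and the medians were 0.40, 0.42 and 0.21. Camera did not call them (p = 0.57, 0.45 and 0.63 at the preset correlation). The others reached 1 RPKM in the nf-ycQ libraries alone. Their rise therefore followed from the filter, and the call over all 14 rests partly on it. With a minimum of 5 RPKM 3 mitochondria-encoded genes were tested and none rose or fell. The median turned to -0.97 and the call ended (camera p = 0.53 at the preset correlation). Without a filter 13 of 63 rose, with a median of 0.18. Without wild-type replicate 3, 9 rose, 2 fell and the camera call ended (p = 0.099 at the preset correlation). Organelle genes took 0.111% to 0.136% of reads in wild type and 0.253% to 0.298% in nf-ycQ. At so small a share, these values cannot separate changed organelle transcript levels from a changed carry-over of organelle RNA into the libraries.

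More genes were higher than lower in nf-ycQ, and the choice of scaling may set this split: 49.8% of called genes were higher after quantile normalization and 44.9% after median-of-ratios scaling. Both move the median log2 fold change towards 0 (0.0327 and 0.0110, against 0.0857 as deposited), which itself evens the split. These shares therefore cannot tell whether the excess of higher genes came from scaling or from transcript levels. A few abundant genes may account for the split in part: the 50 genes with most reads took 17.7% of reads in wild type and 14.4% in nf-ycQ, and without them 50.1% of called genes were higher. Whether they account for all of it stays open, because without them the median log2 fold change of the others was 0.0358, against 0.0857 with them, between the bounds of under 0.03 and at least 0.06 set before this value was seen. Of the 10 splits of the 6 libraries into groups of 3, 1 gave as many genes as the real one in limma, the real one itself with 6188, and likewise 1 for the 863 genes with a 2-fold change. The other splits gave at most 0 genes (at most 1380 at an unadjusted p under 0.05). Each of them mixes the genotypes, so the genotype difference enters the spread within groups and holds calls down. They cannot show what unrelated groups would give, and 10 splits are too few for a share under 0.05.

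Of the seed list 12 of 14 genes rose, and of the abscisic acid list 7 of 11. For the seed list scaling is argued against as the cause, since its median stayed at 1.63 or above under quantile and median-of-ratios scaling. The abscisic acid list was not part of that test. Its rises numbered 6 and 5 under these scalings, with medians of 0.50 and 0.44, against 0.49 as deposited. Slower seedling development stays open: storage reserve mobilisation genes had a median log2 fold change of 0.54 (camera p = 0.0062, and p = 0.21 with an estimated correlation), with 7 of 9 higher and PMDH2 lower (log2 fold change -0.65, adjusted p = 0.0017), and of 29 late embryogenesis genes taken by product name 15 rose and 5 fell, with a median of 0.71 (camera p = 0.018, and p = 0.35 with an estimated correlation). The latter call ended without nf-ycQ replicate 1, 2 or 3, where 24 were tested (camera p = 0.13, 0.14 and 0.41 at the preset correlation, medians 0.08, 0.13 and 0.07, with 10, 9 and 9 rises), without a filter (camera p = 0.052, median 0.17) and with a minimum of 5 RPKM (camera p = 0.38, median 0.10, 6 rises and 3 falls among 15). The late embryogenesis genes that dropped out there reached 1 RPKM in the nf-ycQ libraries alone, so their rise followed from the filter. The falls among late embryogenesis genes numbered 3 without replicate 2 of either genotype and 8 after median-of-ratios scaling. RNA from a few ungerminated seeds stays open: the reads of the 12 seed genes that rose departed from 1 fixed ratio over the nf-ycQ libraries with a chi-square per degree of freedom of 5.10, above the bound of 5 and the 95th percentile of matched random lists, 4.18, but leaving out single genes, a requirement added after that value was seen, gave 4.04 to 5.60, so the result rests on single genes.

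The clock genes CCA1, LHY and RVE8 fell and 10 of the 11 others rose. The median log2 fold change of CCA1, LHY and RVE8 was -0.73 and that of the other clock genes 0.87, a difference of 1.60. A difference in harvest time and an effect of genotype on the clock cannot be told apart by this value, because both allow opposite movements and the labels give no harvest time.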
